A study of Homo sapiens with 6 samples.

How the data were processed

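Gene expression was measured on 6 one-colour microarrays of RNA from A549, an established human lung carcinoma cell line. Per the labels, cells attached for 24 h and were then kept for 48 h in medium with 5.76 µmol/L citreoviridin or with 0.1% DMSO, the solvent of the compound, as control. Each condition had 3 independent cultures, and 0.2 µg of total RNA from each was amplified and labelled with Cy3, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. All 6 arrays lay on 1 slide and came from 1 scan, so neither slide nor scan could differ between the groups. Citreoviridin replicates 1 and 2 lay in slide row 1, and citreoviridin replicate 3 and the 3 DMSO arrays lay in slide row 2.

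The scanner files hold spot intensity values made with Feature Extraction 10.5.1.1, per the file headers. The processed signal is the intensity after background subtraction and spatial detrending within 1 array, with no scaling between arrays, per the file headers and column names. The authors also deposited a value table for the series in log2 units whose processing is not given in the sources used here. Set against the scanner values, this deposited log2 table ranked probes like the median spot signal without background subtraction (rank correlation 0.9994 to 0.9998 per array), its columns had medians of 7.26 to 7.28, and its values were nearly equal in distribution between arrays. It was neither centred per probe nor expressed as a ratio, and it served only as an alternative source.

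The processed signals were transformed to log2, and the array's 75th percentile of non-control spots was subtracted on the log2 scale. Control spots and spots marked as non-uniform or population outliers were left out, and spots of the same probe were averaged. Of 50599 non-control probes on 58717 spots, a probe was tested if it was well above background on all arrays of at least 1 group, which left 39155 probes. A probe with several spots counted as well above background where a share of at least 0.5 of its spots was. A gene was represented by its probe with the highest mean signal, which gave 28833 genes. Symbols were updated from a RefSeq gene table through accession (30004 probes), symbol (3112 probes) or a unique older symbol (487 probes), and 16996 probes kept the name in the file. The table's assembly is newer than the hg19 build of the probe positions, so it was used for names and gene types alone. Of 1219 changed genes with more than 1 tested probe, 12 had another probe past the threshold in the opposite direction.

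The arrays reported 37114 to 42654 probes well above background, the 75th percentile of the processed signal lay between 889 and 1109, and no probe was saturated. The number of arrays, 3 per group, limits the precision.

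Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are differences of mean log2 signal with the moderated standard error (SE). Where a gene was not well above background on any array of a group, a bound is given: the bright group's mean against the dim group's mean, with each dim array's value raised to its lowest signal among probes well above background. The bound holds for the processed signal and does not cover the other background corrections. Before the data were examined, 27 gene lists with 633 members in all were fixed: cell cycle, stress, lipid, mitochondrial, inflammatory and other pathways, and markers of alveolar, fibroblast, blood and endothelial cells. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. The same tests were run with a correlation estimated from the data and with fry. Figures were drawn with matplotlib 3.10.9.

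The rule for named genes was also fixed before the data were examined. Among genes past the threshold with a gene symbol and no overlap between the groups, it took the 6 largest rises and the 6 largest falls. It added the 2 members with the largest change from each of the 8 lists with the lowest camera p that had at least 3 members past the threshold, and ATP5F1B, TXNIP and ARRDC4 whatever their values. Names of transcript models and accessions were read as not being gene symbols. Of the 30 genes the rule took, 2 are not reported here. Other genes are named where few members of a list stood against it, where a list mixed kinds of gene, or in the closing section. These were chosen after their values were seen.

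The alternatives were normexp background correction with an offset of 16, quantile normalization, median scaling, the deposited value table, no filter and a stricter filter on dim probes, the mean of a gene's probes, the replicate number or the slide row as a block, the slide row with both groups alone, a log2 fold of at least 1, an intensity trend with robust eBayes, array weights, both other set tests and leaving out each array. Chosen after seeing the data were scaling to the E1A spike-in spots, leaving out both arrays numbered 1, the replicate block with the trend over probe GC content removed, and the replicate block with an estimated correlation in the set test.

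The labels use the numbers 1 to 3 in both groups without saying what they share. Deviations from the group means correlated at 0.438, 0.194 and 0.102 between arrays of the same number. However, citreoviridin 2 correlated at 0.259 with DMSO 3 and citreoviridin 3 at 0.195 with DMSO 2. The numbers were treated as possible pairs. The main fit has no block, so its counts, SEs and p-values are unpaired. The alternative fit with the replicate block called 3169 genes higher and 2907 lower.

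The fit and set test were checked on 20 simulated experiments of 28833 genes with 200 changed genes, drawn from the spread of the comparison between citreoviridin and DMSO. They recovered 44.5% of genes changed by 1 on the log2 scale and 90.2% of genes changed by 2, with 6.5 false calls on average. A list of 31 genes shifted by 0.5 was found in 100% of simulations. These simulations held no correlation between genes. They also held 200 changed genes, against 4318 called in the data, so the recovery rates need not hold for the data.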

Results

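Citreoviridin is a fungal polyene mycotoxin that binds the beta subunit of the mitochondrial ATP synthase and inhibits the enzyme. The series asked how gene expression in A549 lung carcinoma cells differs after 48 h with 5.76 µmol/L citreoviridin from that with 0.1% DMSO. It holds 6 arrays, 3 independent cultures per condition, with 37114 to 42654 probes well above background on each array. The first principal component held 53.4% of the variance and separated the conditions, and the second held 25% and set the arrays numbered 1 apart from the others. Probe positions are given on hg19 as in the deposited files, and their place in exons was not analysed here.

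Citreoviridin-treated cells had higher mRNA of 2280 genes and lower mRNA of 2038 genes than DMSO-treated cells, 15% of the 28833 genes tested (limma, adjusted p under 0.05). Of these, 586 rose and 548 fell by at least 1 on the log2 scale, and 1784 of those that rose and 1535 of those that fell were protein-coding. The groups' values did not overlap for 9974 genes, against 10% of genes by chance. The largest rise was that of NIBAN1, a stress-induced regulator of translation, whose log2 signal was 2.99 ± 0.18 with citreoviridin and -2.59 ± 0.23 with DMSO (SD, n = 3), a 47.8-fold difference (probe at chromosome 1, 184760227 to 184760286). IL1RL1, the receptor of interleukin 33, was not well above background in DMSO and was at least 6.88-fold higher with citreoviridin on the processed signal, with a fitted log2 change of 2.19 to 4.36 over 20 alternatives. FUT1, a fucosyltransferase of H antigen synthesis, was 13.3-fold higher and STC2, a secreted glycoprotein induced by stress, 11.2-fold. The probe for RNU2-1, the U2 spliceosomal RNA, was 12.7-fold higher, but this RNA has near-identical copies and the probe lies on chromosome 11, so its source is uncertain.

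Genes of secreted liver-type proteins were among the largest falls. FGA and FGB, which encode chains of fibrinogen, had log2 changes of -4.72 ± 0.49 and -3.55 ± 0.32 (SE, limma adjusted p 0.00191 and 0.00115). FGA, on chromosome 4 (155507248 to 155507307), and FGB were each well above background on 1 of the 3 citreoviridin arrays, and over 20 alternatives each their log2 change ran from -5.41 to -2.70 and from -3.97 to -2.48. CFI, complement factor I, was not well above background with citreoviridin and was at least 3.29-fold lower on the processed signal, with a fitted log2 change of -3.94 to -1.40 over 20 alternatives. BAAT, the enzyme that conjugates bile acids, had a log2 change of -3.46 ± 0.12 and TM4SF4, a tetraspanin-like membrane protein, one of -3.27 ± 0.29 (SE, limma adjusted p 8.41e-05 and 0.00102), the former running from -3.79 to -2.58 over 21 alternatives. CNGA2, a cyclic nucleotide-gated channel subunit, was at least 3.89-fold lower on the processed signal, but its DMSO values had an SD of 1.96. Its adjusted p of 0.0449 went from 0.0169 to 0.166 and its fitted log2 change from -4.28 to -1.47 over 20 alternatives. The smallest changes of FGA, FGB, CFI, BAAT and CNGA2 came from normexp background correction or the deposited value table.

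**Figure D1:**
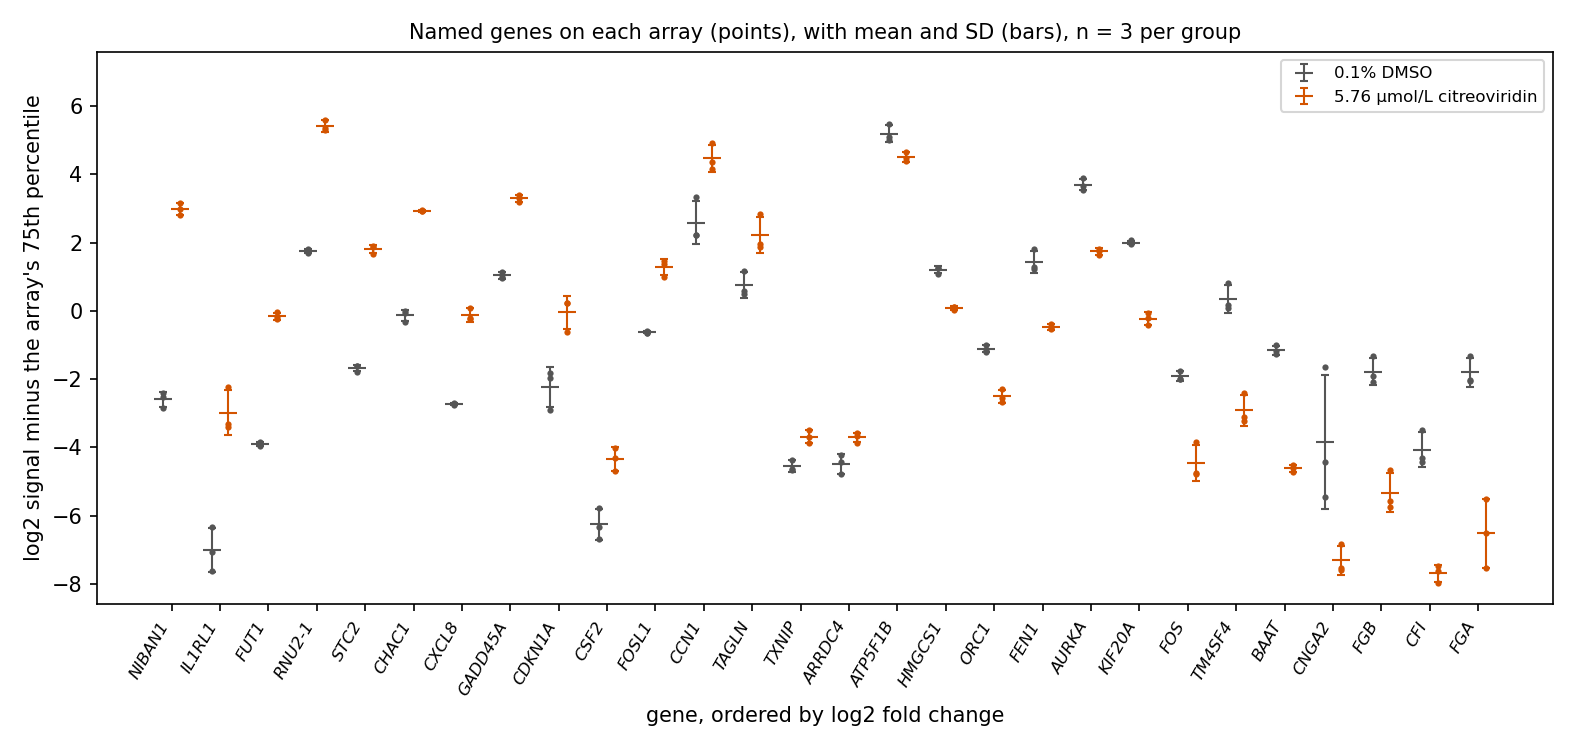
Log2 signal minus the array's 75th percentile (vertical axis) of the named genes (horizontal axis, ordered by log2 fold change). Points are arrays, and bars are the mean and SD of 3 citreoviridin (orange) or 3 DMSO (grey) arrays. The group means of NIBAN1 differ by 5.58 and those of FGA by -4.72 on the processed signal, and CNGA2 in DMSO has an SD of 1.96.

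The counts depended on single arrays and on the scaling. Leaving out 1 array gave 952 to 2196 higher and 847 to 3032 lower genes, and the counts were 1174 and 867 without citreoviridin 2, 1693 and 1334 without citreoviridin 3, 981 and 851 without DMSO 2, and 952 and 847 without DMSO 3. Of the called genes, 52.8% were higher, 42% without citreoviridin 1 or with the slide row as a block, and 38.4% within the slide row that holds both groups. The slide row as a block and the row that holds both groups leave citreoviridin 3 alone to be set against DMSO, assumed to vary like the other arrays, so a call can be lost there without a smaller change. Scaling to the E1A spike-in spots, a choice made after seeing the data, moved the median of all genes to -0.37 on the log2 scale and gave 496 higher and 3979 lower genes, 11.1% higher, so all rises and falls here are relative to the signal of each array. Without both arrays numbered 1, another choice made after seeing the data, 3343 genes were higher and 3587 lower.

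Targets of the integrated stress response, the programme of the transcription factors ATF4 and CHOP, rose together. Of 37 tested members 31 rose, none fell and 6 did not pass (34 rose and 0 fell adjusted over the list alone), with a median log2 change of 1.33 (camera adjusted p 4.13e-30). STC2 rose by 3.49 ± 0.12 and CHAC1, an enzyme that degrades glutathione, by 3.06 ± 0.12 on the log2 scale (SE, limma adjusted p 8.33e-05 and 0.000159), and that of CHAC1 was 2.35 to 3.13 over 21 alternatives. The list held with an estimated correlation (adjusted p = 0.0105), but not when this was combined with the replicate block (adjusted p = 0.185, range over 24 alternatives 2.46e-48 to 0.185). This combination leaves few degrees of freedom to estimate a correlation from 6 arrays. All 13 lists that passed the main set test lost their call under it, so the loss says little about a single list. ER chaperones and ER-associated degradation genes did not move as a list (camera adjusted p 0.945). Of its 26 members 4 rose, 2 fell and 20 did not pass (5 rose and 3 fell adjusted over the list alone), with a median of -0.12 and a mean near 0 of the opposite sign. In the main fit the 4 that rose were HERPUD1 (1.30), XBP1 (0.96), HSPA5 (0.84) and DNAJB9 (0.57). The 2 that fell were PDIA6 (-0.64) and CALR (-0.57), and all were named after their values were seen.

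Genes of mitosis and of DNA replication fell. All 40 mitosis and G2/M genes fell (40 also adjusted over the list alone), with a median of -1.35 (camera adjusted p 8.94e-34). This call was lost with an estimated correlation (adjusted p = 0.0576), and combined with the replicate block (adjusted p = 0.314, range over 24 alternatives 3.77e-40 to 0.314). KIF20A, a kinesin of cytokinesis, fell by 2.23 ± 0.13 and AURKA, a mitotic kinase, by 1.95 ± 0.13 on the log2 scale (SE, limma adjusted p 0.000299 and 0.000402). Of 40 E2F targets of DNA replication and S phase 37 fell, none rose and 3 did not pass (40 fell adjusted over the list alone), with a median of -0.88 (camera adjusted p 5.98e-24). This call was lost with an estimated correlation (adjusted p = 0.131), and combined with the replicate block (adjusted p = 0.385, range over 24 alternatives 1.29e-27 to 0.385). Among them FEN1, the flap endonuclease, fell by 1.91 ± 0.17 and ORC1, of the origin recognition complex, by 1.40 ± 0.14. The count of 37 replication genes became 21 with the slide row as a block, 24 without citreoviridin 2 or without DMSO 2 and 23 without DMSO 3. The median was -0.92 with the slide row as a block and -1.21 to -0.83 over 24 alternatives.

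Targets of p53 rose as a list. Activity of p53 was not measured, and whether another stress programme raised these genes was not tested. Of 26 tested members 16 rose, none fell and 10 did not pass, with a median of 0.68 (camera adjusted p 6.07e-12). Adjusted over the list alone 19 rose and 1 fell (CCNG1, -0.40). With E1A scaling 7 rose, with a median of 0.35. There were 10 that rose with the slide row as a block, within the slide row that holds both groups, without DMSO 2 or without DMSO 3, where the medians were 0.68 to 0.69. GADD45A, a growth arrest gene, was 4.78-fold higher and CDKN1A, the cyclin-dependent kinase inhibitor p21, was 4.53-fold higher, with log2 changes of 2.26 ± 0.11 and 2.18 ± 0.35 (SE, limma adjusted p 0.000267 and 0.00897). The list held with an estimated correlation (adjusted p = 0.0272) and was lost when this was combined with the replicate block (adjusted p = 0.266, range over 24 alternatives 9.44e-17 to 0.266).

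Genes of sterol and fatty acid synthesis fell. Of 24 SREBP2 targets of cholesterol synthesis and uptake 16 fell, none rose and 8 did not pass (19 fell and 0 rose adjusted over the list alone), with a median of -0.72 (camera adjusted p 3.53e-10). This call was lost with an estimated correlation (adjusted p = 0.0576), and combined with the replicate block (adjusted p = 0.266, range over 24 alternatives 1.5e-11 to 0.266). Of the 24, 6 fell with the slide row as a block, 8 within the slide row that holds both groups, 7 without citreoviridin 2 or without DMSO 2 and 8 without DMSO 3. The median was -0.75 with the slide row as a block and -1.05 to -0.66 over 24 alternatives. HMGCS1, an enzyme of the mevalonate pathway, fell by 1.12 ± 0.11 on the log2 scale (SE, limma adjusted p 0.00125). Of 14 SREBP1 targets of fatty acid synthesis 7 fell and 7 did not pass (7 fell and 1 rose adjusted over the list alone), with a median of -0.33 (camera adjusted p 0.000383). This call was lost with an estimated correlation (adjusted p = 0.124), and combined with the replicate block (adjusted p = 0.412, range over 24 alternatives 9.4e-05 to 0.412). Of the 14, 4 fell with the slide row as a block or without citreoviridin 2, DMSO 2 or DMSO 3. The median was -0.54 with the slide row as a block and within the row that holds both groups and -0.66 with E1A scaling.

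Inflammatory, mesenchymal and immediate early genes rose as lists, with exceptions. Of 25 inflammatory cytokine and NF-kB genes 13 rose, 2 fell and 10 did not pass (16 rose and 2 fell adjusted over the list alone), with a median of 0.62 (camera adjusted p 3.63e-08), and with E1A scaling 6 rose, with a median of 0.29. CXCL8, the chemokine interleukin 8, rose by 2.61 ± 0.13 and CSF2, the cytokine GM-CSF, by 1.91 ± 0.27 (SE, limma adjusted p 0.000267 and 0.00558), CSF2 being above background on 1 of 3 DMSO arrays and rising by 0.89 to 2.16 over 20 alternatives. The 2 that fell, named after their values were seen, were PTGS2, a cyclooxygenase (-1.72), and CCL2, a chemokine (-0.65). The list held with an estimated correlation (adjusted p = 0.0272) and was lost when this was combined with the replicate block (adjusted p = 0.266, range over 24 alternatives 1.22e-11 to 0.266). Of 23 mesenchymal and TGF-beta response genes 10 rose, 1 fell (SNAI1, a repressor of E-cadherin, -1.08) and 12 did not pass (13 rose and 2 fell adjusted over the list alone), with a median of 0.48 (camera adjusted p 2.14e-05). This call was lost with an estimated correlation (adjusted p = 0.0797), and combined with the replicate block (adjusted p = 0.266, range over 24 alternatives 1.58e-06 to 0.266). With E1A scaling 3 rose and 2 fell, with a median of 0.15. In the same list 4 rose with the slide row as a block or within the row that holds both groups, 5 without DMSO 2 or without DMSO 3, and 16 with array weights, where the medians were 0.43 to 0.47. CCN1, a matricellular protein, was 3.69-fold and TAGLN, an actin-binding protein, 2.77-fold higher. Their limma adjusted p of 0.0141 and 0.0204 reached 0.0936 and 0.135 over 21 alternatives each. These calls were lost with the slide row as a block, within the row that holds both groups, and without DMSO 2 or DMSO 3. Of 19 immediate early genes 7 rose, 1 fell and 11 did not pass (11 rose and 2 fell adjusted over the list alone), with a median of 0.65 (camera adjusted p 0.00027). This call was lost with an estimated correlation (adjusted p = 0.0576), and combined with the replicate block (adjusted p = 0.266, range over 24 alternatives 1.42e-05 to 0.266). With E1A scaling 4 rose, with a median of 0.32, while 11 rose with the replicate block and 12 with array weights. FOSL1 rose by 1.91 ± 0.14 while FOS, another subunit of the AP-1 transcription factor, fell by 2.55 ± 0.26 on the log2 scale (SE, limma adjusted p 0.000652 and 0.00177), and the change of FOS was -2.87 to -1.94 over 21 alternatives.

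A further 4 lists passed the set test. Of 26 NRF2 targets 7 fell, 1 rose (ABCC3, a transporter, 0.59) and 18 did not pass (10 fell and 2 rose adjusted over the list alone), with a median of -0.25 (camera adjusted p 0.00235, adjusted p = 0.408 with an estimated correlation). Of 19 cytosolic and mitochondrial heat shock proteins 7 fell, 1 rose (LONP1, a mitochondrial protease, 0.80) and 11 did not pass (9 fell and 1 rose adjusted over the list alone), with a median of -0.30 (camera adjusted p 0.00241, adjusted p = 0.331 with an estimated correlation). Those that fell were HSPA1A, HSPA1B, HSPH1, HSP90AA1, HSP90AB1, DNAJA1 and BAG3, none of them a mitochondrial member. The mitochondrial members HSPE1 (-0.62), TRAP1 (-0.23), HSPD1 (-0.13), CLPP (0.21) and HSPA9 (0.28) did not pass. Of 14 xenobiotic metabolism genes 5 fell, 1 rose (TIPARP, 0.89) and 8 did not pass (6 fell and 1 rose adjusted over the list alone), with a median of -0.46 (camera adjusted p 0.04, adjusted p = 0.254 with an estimated correlation). Of 31 autophagy and lysosome genes 7 rose, 1 fell (ATP6V1H, a subunit of the lysosomal proton pump, -0.61) and 23 did not pass (7 rose and 2 fell adjusted over the list alone), with a median of 0.19 (camera adjusted p 0.0055, adjusted p = 0.564 with an estimated correlation) that turned to -0.14 with E1A scaling. It was 0.13 in the deposited value table. The counts of 7 NRF2 and 7 heat shock genes that fell, 5 xenobiotic metabolism genes that fell and 7 autophagy genes that rose were 2, 3, 2 and 4 with the slide row as a block. They were 2, 2, 2 and 4 within the row that holds both groups and 17, 12, 9 and 14 with array weights. Without citreoviridin 2 they were 3, 3, 2 and 4, without DMSO 2 they were 3, 3, 1 and 4, and without DMSO 3 they were 2, 4, 2 and 3. Without citreoviridin 3 the counts of NRF2 and xenobiotic metabolism were 4 and 3. With E1A scaling 1 autophagy gene rose and 8 xenobiotic metabolism genes fell. There the medians of the NRF2, heat shock and xenobiotic metabolism lists were -0.58, -0.63 and -0.79. The NRF2 count was 14 after quantile normalization and 12 in the deposited value table, with medians of -0.43 in both. The xenobiotic count was 3 without the filter on dim probes and 8 without both arrays numbered 1. The xenobiotic call was also lost without citreoviridin 1 (adjusted p 0.0969), without DMSO 3 (adjusted p 0.076) and with E1A scaling (adjusted p 0.0527). The NRF2 call was lost without both arrays numbered 1 (adjusted p 0.0526). The autophagy call was lost with normexp background correction (adjusted p 0.072) and in the deposited value table (adjusted p 0.0867), with a range of 0.00171 to 0.564 over 24 alternatives. With an estimated correlation and the replicate block combined, the adjusted p was 0.412 for NRF2, 0.385 for heat shock, 0.536 for xenobiotic metabolism and 0.385 for autophagy. With the slide row as a block, the adjusted p was 0.16 for NRF2, 0.0948 for heat shock and 0.251 for xenobiotic metabolism. Within the row that holds both groups these were 0.219, 0.128 and 0.237, with medians of -0.26, -0.30 and -0.56 in both. Over 24 alternatives each, the ranges were 1.71e-06 to 0.412, 0.000103 to 0.385 and 0.0101 to 0.536.

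**Figure D2:**
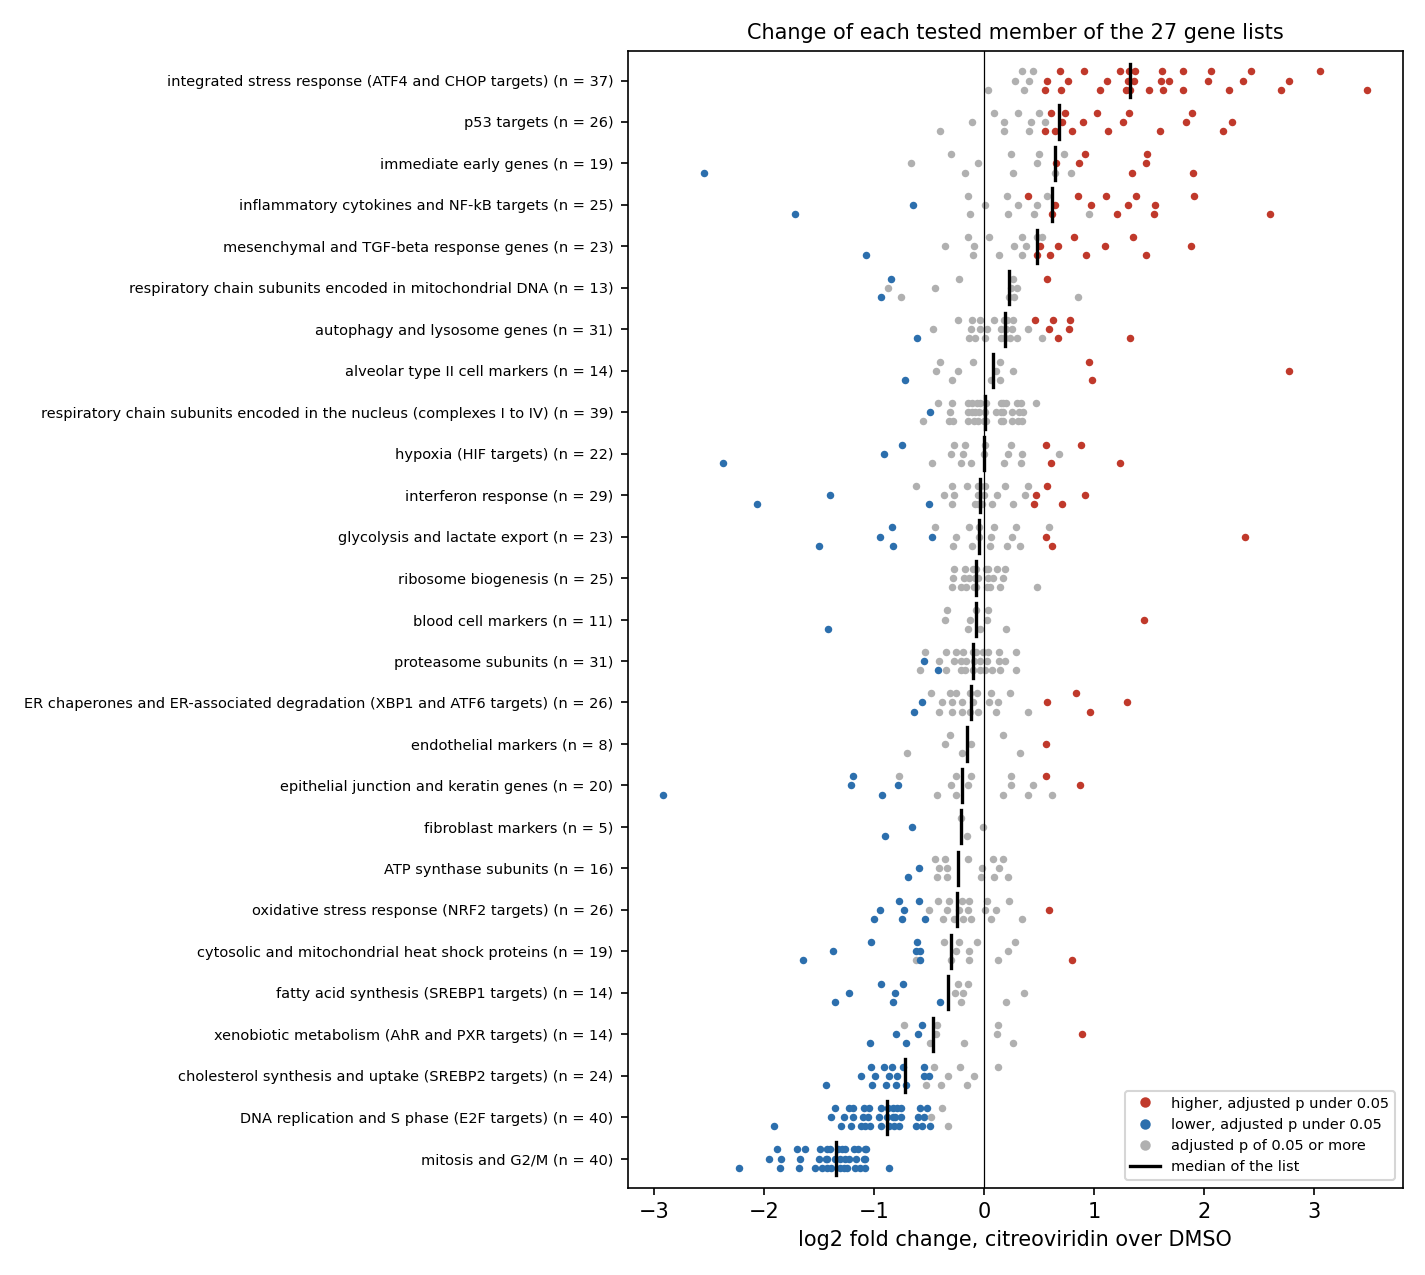
Log2 fold change of citreoviridin over DMSO (horizontal axis) of each tested member of the 27 gene lists (vertical axis). Red and blue points are genes higher and lower with adjusted p under 0.05, grey points did not pass, and black bars are list medians. The integrated stress response list has the highest median, 1.33, and the mitosis list the lowest, -1.35, relative to each array's own signal.

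ATP5F1B, the beta subunit of ATP synthase to which citreoviridin binds, was 1.61-fold lower (log2 change -0.69 ± 0.16 SE, limma adjusted p 0.0313). Its log2 signal was 4.51 ± 0.15 with citreoviridin and 5.20 ± 0.25 with DMSO (SD, n = 3), and its adjusted p ranged from 0.000668 to 0.191 over 21 alternatives, 9 of which lost the call. Of 16 members of the ATP synthase list 2 fell, ATP5F1B and ATP5F1C (-0.59), and 14 did not pass (none passed adjusted over the list alone). The count that fell was 4 after quantile normalization, 6 in the deposited value table, 8 with array weights and 0 without the filter on dim probes. The median of these members ran from -0.57 to -0.07 over 24 alternatives. One member, ATP5IF1 (0.17), is an inhibitor of the enzyme and not a subunit. The subunits ATP6 (-0.445) and ATP8 (-0.875) are counted with mitochondrial DNA below, and neither passed over all genes (limma adjusted p 0.0873 and 0.0501). The list, with a median of -0.24, had a camera adjusted p of 0.208, but 0.00219 after quantile normalization and 0.00549 in the deposited value table (range over 24 alternatives 0.00219 to 0.945). Of 39 nuclear respiratory chain subunits 1 fell (SDHD, -0.49) and 38 did not pass (none adjusted over the list alone, camera adjusted p 0.803). In this list 1 rose and 7 fell after quantile normalization, and 1 rose and 6 fell in the deposited value table. With E1A scaling 4 fell and none rose, and with array weights 10 rose and 7 fell. The list's median ran from -0.32 to 0.15 and its adjusted p from 0.0636 to 0.993 over 24 alternatives. Of 13 subunits encoded in mitochondrial DNA ND4 rose (0.58), COX2 (-0.94) and COX3 (-0.85) fell and 10 did not pass (1 rose and 5 fell adjusted over the list alone, camera adjusted p 0.648), with a median of 0.23 and a mean of -0.10. TXNIP and ARRDC4, paralogous arrestins that respond to glucose metabolites, were 1.82-fold and 1.71-fold higher (limma adjusted p 0.0101 and 0.0262). Their adjusted p reached 0.0848 and 0.3 over 21 alternatives each, with 5 and 8 losing the call.

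The remaining lists did not pass the set test. Of 23 glycolysis and lactate export genes 3 rose, with HK2 at 2.38, and 5 fell, with PFKFB3 at -1.51. Adjusted over the list alone 4 rose and 5 fell (camera adjusted p 0.992). Of 22 HIF targets 4 rose, with VEGFA at 1.24, and 3 fell, with CA9 at -2.38 (5 rose and 4 fell adjusted over the list alone, camera adjusted p 0.808). Of 29 interferon response genes 5 rose and 3 fell, with IFIT1 at -2.07 (5 rose and 3 fell adjusted over the list alone, camera adjusted p 0.945). Of 20 epithelial junction and keratin genes 2 rose and 5 fell, with CLDN2 at -2.92 and CDH1, which encodes E-cadherin, at -0.93 (4 rose and 7 fell adjusted over the list alone, camera adjusted p 0.217, fry adjusted p 0.0285, 0.0471 in the deposited value table, range over 24 alternatives 0.0285 to 0.767). Of 31 proteasome subunits 2 fell, PSMD6 (-0.55) and PSMA3 (-0.42) (1 fell adjusted over the list alone, camera adjusted p 0.217). The list passed after quantile normalization (adjusted p 0.00672, 5 fell), in the deposited value table (0.00418, 8 fell) and with normexp correction (0.0492, 4 fell), with a range of 0.00418 to 0.974 over 24 alternatives. None of 25 ribosome biogenesis genes passed (none adjusted over the list alone, camera adjusted p 0.803). These single genes were named after their values were seen.

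Markers of cell types were given the same test. Of 14 alveolar type II cell markers LAMP3 (2.78), ABCA3 (0.98) and ETV5 (0.96) rose and LPCAT1 (-0.72) fell (3 rose and 1 fell adjusted over the list alone, camera adjusted p 0.397). Of 5 tested fibroblast markers COL1A1 (-0.90) and THY1 (-0.65) fell (2 fell adjusted over the list alone, camera adjusted p 0.0851, fry adjusted p 0.028, 0.028 without DMSO 3, range over 23 alternatives 0.028 to 0.707). Of 11 blood cell markers CD68 (1.46) rose and CD14 (-1.42) fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p 0.803). Of 8 endothelial markers ESAM (0.56) rose (1 rose adjusted over the list alone, camera adjusted p 0.992).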

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

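The tests here were written down before their values were seen, except that on the pair within 1 slide row, and the pattern itself was noticed in the data. The E1A spike-in spots, control RNA spots that the comparisons do not use, were brighter relative to the genes in citreoviridin-treated samples. The array's 75th percentile minus the mean of 350 E1A spots differed by -0.33 on the log2 scale, with -1.58 ± 0.28 with citreoviridin and -1.25 ± 0.27 with DMSO (SD, n = 3, two-sided exact permutation p = 0.3, the smallest possible being 0.1), and all 3 same-numbered pairs went one way, by -0.34, -0.33 and -0.32 (exact sign-flip p = 0.25, the smallest that 3 pairs allow). If the numbers mark pairs, dim spike-in spots near the background are argued against, since the 5 brightest of 10 spike-in probes gave -0.40, with -0.28, -0.38 and -0.53 for the pairs (SD 0.13). Without pairing this stays open. Against the 5 brightest, the arrays stood at -6.12, -5.61 and -5.74 with citreoviridin and -5.84, -5.23 and -5.21 with DMSO, which overlap. The position on the slide, its row included, stays open, since the row that holds both groups has 1 citreoviridin array. That array, citreoviridin 3, differed by -0.32 from DMSO 3 and by -0.18 from the mean of the 3 DMSO arrays. A lower share of amplifiable mRNA in total RNA under citreoviridin, or a difference in RNA input or in the amount of spike-in added, was not tested.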

How the results depend on the processing

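The E1A scaling, leaving out both arrays numbered 1, the replicate block with the GC trend removed and the replicate block with an estimated correlation were chosen after seeing the data. No named gene changed its direction, and no called list changed the direction of its set test, under any alternative run, although the autophagy list's median turned negative with E1A scaling. Of 30 named genes 24 kept an adjusted p under the threshold in every alternative that tested them, and the other 6 (CNGA2, ATP5F1B, ARRDC4, TXNIP, CCN1 and TAGLN) lost it in some, in 42 of the comparisons made against 582 that kept it. The counts of higher and lower genes stayed within 1.5 times of 2280 and 2038 except as follows. The fold minimum lowers counts by construction, and for the other alternatives the cause was not tested. They were 918 and 1269 with the slide row as a block, 586 and 548 with a log2 fold of at least 1, 7032 and 8381 with array weights, and 496 and 3979 with E1A scaling. Within the slide row that holds both groups 1100 genes were higher, and without both arrays numbered 1 3587 were lower. Leaving out each array in turn gave 952 to 2196 higher genes, 847 to 3032 lower genes and 12 to 13 lists. The replicate block gave 3169 higher and 2907 lower genes and 13 lists, 96.7% of the called genes remained, and apart from CNGA2 (adjusted p 0.0589, range 0.0169 to 0.166) it changed no call of a named gene or list with the preset correlation. The count of lists past the set test was 13, but 3 with an estimated correlation and 0 with the estimated correlation and the replicate block together, and 15 with fry. The count of 0 says little about the lists, since the block leaves few degrees of freedom to estimate the correlation from 6 arrays. A gene well above background in 1 group alone has a bound in place of a fold, which was so for 56 called genes.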

Other observations

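The gene groups in this part were assembled after the largest changes had been seen, and the tests on small nucleolar RNAs and on the 9 liver-type genes already seen were also chosen after the result was seen. Members already seen are kept apart from the others. Replication-dependent histone genes, whose expression is tied to S phase, fell in 29 of 61 tested cases and rose in none, with a median of -0.53 (fry p 0.00128, camera p = 0.0447 with an estimated correlation), but all had been seen beforehand and near-identical copies share probes. Among Wnt and beta-catenin targets RNF43 and AXIN2, feedback inhibitors of the pathway, had been seen to fall, by 8.03-fold and 5.56-fold. Of the 14 others 3 fell, 1 rose and 10 did not pass, with a median of -0.25 (fry p 0.0221, camera p = 0.37 with an estimated correlation).

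Host genes of small nucleolar RNAs, whose spliced transcripts are degraded by nonsense-mediated decay, included GAS5 (2.40), SNHG32 (2.41) and ZFAS1 (2.21), which had been seen to rise. Of the 20 others 8 rose, 2 fell and 10 did not pass, with a median of 0.47 (95% interval -0.35 to 0.72, fry p 0.0322, camera p = 0.341 with an estimated correlation), under the 0.5 set beforehand for calling the rise general, so this stays open. Lower activity of the decay pathway, a candidate explanation, predicted a joint rise of its factors UPF and SMG, some of whose mRNAs it degrades. Their median was -0.11 (-0.35 to 0.11), with 1 of 10 lower (UPF1, -0.66) and none higher, so the predicted rise was not seen. These mRNAs are an indirect measure of decay, so this argues against lower activity only as far as they report it. Better recovery of RNA without a poly(A) tail stays open: 267 small nucleolar RNAs had a median of 0.16 (0.10 to 0.25). The interval of the host genes' median (0.58, 0.19 to 1.04, with the 3 seen to rise) overlaps theirs. This explanation reaches the host genes only if their probes read RNA without such a tail, which was not tested, so the comparison cannot decide it. Slower translation, which would also stabilise such transcripts, was not tested.

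The group of liver-type secreted and bile acid genes included 9 that had been seen to fall, with a median of -3.27. They were FGA, FGB, FGG, APOH, CFI, CP, BAAT, CPS1 and TM4SF4. The name of the group is loose, since TM4SF4 is a membrane protein and CPS1 a mitochondrial enzyme. Of the 32 others 6 fell, none rose and 26 did not pass, with a median of -0.21 (-0.28 to -0.03, fry p 0.0785, and 0.0136 with the replicate block, camera p = 0.461 with an estimated correlation), so the bound of -0.3 set beforehand for the median in a general fall was not met in either case. Removing the trend over probe GC content in the fit with the replicate block gave -0.27 over all 41 members, but the median had been -0.26 before, already past the bound set for that explanation, so over all members the test decides nothing. For the 9 members alone a GC trend is argued against as the whole cause, since they stood at -3.33 after it was removed. The trend removed was small: the log2 change of all genes moved by a median of 0.025, so these 9 calls were unlikely to be lost in that fit. The background treatment is argued against as the whole cause too, since their median was -2.50 with normexp correction and -2.48 in the deposited value table, and all 9 stayed past the threshold in each of these fits. A stricter bound was tried first, that the upper limit of their median stay under -1.63, which is 0.5 times -3.27. The GC fit met it (-2.12), but the normexp correction (-1.63) and the deposited value table (-1.54) did not clear it, so the background treatment may account for part of the size. The slide row stays open: with it as a block their median was -3.46, but this sets citreoviridin 3 alone against DMSO. Liver transcription factors had a median of -0.46 (-0.81 to 0.08), with 4 of 10 lower and none higher (fry p 0.00188, camera p = 0.0682 with an estimated correlation), which met the bound set beforehand, so lower mRNA of these factors may accompany the fall. Each of the 9 genes passed the adjustment over all tested genes in the main fit (highest limma adjusted p 0.00259), so their falls stand as single calls, with the slide row open. A fall of liver-type genes as a group remains a hypothesis, since the 9 were picked for their fall. Whether the fall extends to the others stays open.

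The 10 splits of the 6 samples into groups of 3 are too few for a share under 0.05. The real split gave 4318 genes past the threshold (8213 at an unadjusted p under 0.05) and the others at most 0 (limma, 85 to 1854 at an unadjusted p under 0.05), so 1 of 10 gave as many. The other splits that part all 3 pairs had 85 to 533 genes at an unadjusted p under 0.05. For lists with the preset correlation, the real split gave 13 and the others 5 to 13, so 2 of 10 gave as many, and with an estimated correlation the real split gave 3 lists and each other split 0. Every other split mixes the groups unevenly, so part of the difference between citreoviridin and DMSO stays in it. Lists that passed there can reflect that difference or false calls, which these splits cannot tell apart.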
